A study of Gallus gallus with 6 samples.

How the data were processed

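Gene expression was measured on 6 arrays of chicken macrophages derived from peripheral blood, 5 with a pair of RNA samples and 1 with a single labelled sample, per the labels. Groups were taken from the labels, and each held 1 array, so no test between groups was possible and the number of arrays limits the precision. The deposited table held 14718 spots and 1 column per array. For the arrays with 2 channels the values were taken as log2 ratios made by the authors; the base of the logarithm was not stated and base 2 was assumed, since only 1 spot exceeded 16 in size, and another base would ask for larger ratios. The array of LPS 2 h held deposited values on a linear intensity scale, 204 of them below 0, as after a background subtraction. Per the labels, channel 1 held E. coli 1 h, E. coli 2 h, unstimulated cells, E. coli 4 h and E. coli 8 h on the 5 ratio arrays, and channel 2 the other RNA. The title of the E. coli 1 h array names the control first, against its channel order, while the other ratio arrays have titles in channel order. The numerator, dyes, normalization, background correction and filters are not given in the sources used here, and scale, centring and direction thus remain unknown. Median ratios as deposited were 0.07 for the E. coli 1 h array, 0.49 for E. coli 2 h and 4 h, 0.29 for LPS 1 h, -0.11 at 4 h and 0.12 at 8 h.

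A probe table with an annotation of 2007 listed 9069 spots, of which 9066 had 1 gene and 3 had several, and the 5649 spots it did not list had no gene name here. Spots with several genes were not named. Symbols were updated by gene identifier through a RefSeq table of the assembly GRCg7b, which matched 2228 of 2255 identifiers and served for names only, with no coordinates. Paralogues of the CCL4 family can cross-hybridise on cDNA clones, and their values are uncertain in that respect. Identifiers showed 4906 clones with 3 spots each. Each array's log2 ratios were centred on the array's median, spots were averaged within a clone and clones within a gene, which left 2253 genes. The SD is over all spots of a gene on 1 array. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

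A gene counted as past 2-fold when its centred log2 ratio was at least 1 in size. For each of the lists of genes, the median ratio was set against 10000 random lists of the same size drawn from the same 20 bins of LPS 2 h intensity, and its percentile describes that array and is no p-value. There were 25 lists: inflammatory cytokines and chemokines, NF-kB pathway, toll-like receptor signalling, immediate early genes, interferon response, antigen presentation, lysosome and phagocytosis, oxidative and antimicrobial effectors, actin cytoskeleton and adhesion, matrix and remodelling, cell survival and death, heat shock and unfolded protein response, glycolysis, oxidative phosphorylation, ribosomal proteins, proteasome, cell cycle, and markers of macrophages, T cells, B cells, thrombocytes, erythroid cells, heterophils, dendritic cells and stromal cells. Of these 24 had at least 3 measured genes. Some members were matched through a synonym of the table and carry the table's symbol, such as S100A12 in the heterophil list. SH2D6 stands for BLNK in the B cell list and ALAS1 for ALAS2 in the erythroid list, and these may be other genes than those meant. Pearson's r was computed across genes for 10 pairs of arrays, with 95% intervals from 1000 bootstrap resamples of genes. Overlaps were set against the product of the counts over the number of genes read on both arrays. For arrays that share an RNA sample, 3 RNA samples of equal deviation and no effect were simulated 100 times with each array's own spread. All of the spread went to the RNA samples, with no spot noise or intensity trend, so an r near -0.50 was fixed in advance.

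Lists, thresholds, the rule for naming genes and all alternatives but 1 were chosen before the data were examined. The rule named, per array, the 10 genes with the largest positive and the 10 with the largest negative ratios among those past 2-fold whose spots all shared 1 sign. It added every member past 2-fold of the cytokine, NF-kB, toll-like receptor, immediate early and interferon lists, and 2 to 4 members of largest absolute ratio from each other list described on an array. The matrix list departs from this, with more members named on the E. coli 2 h and 4 h array and on the 4 h array, and not all by size. Of the genes with the largest ratios the text gives a part, picked after their values were seen, and lists given by the range of their medians have no examples. Genes named again on another array, and the brightest genes at LPS 2 h, stand beside these for comparison.

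The steps were tested on simulated data in which genes were given known log2 changes of 1.5, 2 and 3 with the spot noise of each array. On the E. coli 1 h array 97.0%, 100% and 100% of changed genes were found past 2-fold with the right sign, and 2.58% of unchanged genes. On the E. coli 2 h and 4 h array these were 95.5%, 95.5% and 100%, and 6.28% of unchanged genes. On the LPS 1 h array they were 94.0%, 100% and 100%, and 2.05%. On the 4 h array they were 94.0%, 95.5% and 98.5%, and 7.99%, and on the 8 h array 88.1%, 97.0% and 98.5%, and 8.77%. Each array had 67, 67 and 66 changed genes at these sizes and 2053 unchanged ones. The simulated spots had no intensity trend and no variation between cultures, so the shares of unchanged genes hold for spot noise alone and can be too low. A list of 15 genes moved by a log2 of 1 on the E. coli 1 h array reached percentile 100, and 4 of 100 random lists there fell outside the central 95%.

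Alternatives were ratios without centring, thresholds of 1.5-fold and 3-fold, arrays scaled to the mean of their median absolute deviations, the median of a gene's spots, each spot by itself, spots with a value in all 6 columns, removal of the dimmest 25% of spots, Spearman's rho, removal of the 1% of genes with the largest ratios, and the sign of 1 array turned. After the values had been seen, removal of the intensity trend was added, as a lowess curve with a fraction of 0.3 fitted on the rank of LPS 2 h intensity. Since that intensity comes from stimulated cells, the curve can also remove part of a real difference.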

Results

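Gene expression was measured in macrophages grown from chicken peripheral blood and exposed to whole E. coli of the XL10 laboratory strain or to lipopolysaccharide (LPS), the cell wall glycolipid of Gram-negative bacteria, taken from S. typh. Times of 1, 2, 4 and 8 h were sampled beside unstimulated cells, and the stimulus was taken off after 2 h for the later times. Total RNA was hybridised to 6 spotted cDNA arrays, each the only one of its kind. On 5 of them a pair of RNA samples was compared: E. coli 1 h with unstimulated cells (the E. coli 1 h array), unstimulated cells with LPS 1 h (the LPS 1 h array), E. coli 2 h with E. coli 4 h (the E. coli 2 h and 4 h array), E. coli 4 h with LPS 4 h (the 4 h array) and E. coli 8 h with LPS 8 h (the 8 h array). The sixth gave the intensity of LPS 2 h alone.

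With 1 array per comparison there was no replicate and no test, and the number of arrays limits the precision. Each ± is the SD over the spots of a gene on 1 array and holds technical spread only. For genes with several clones, such as IL8L1 and IL1B with 2 each, this includes differences between clones. Ratios are log2 values centred on the array's median, with base 2 assumed. Neither the numerator nor the dyes were stated, so the direction is unsettled and signs are as deposited. If an array ran the other way, each of its ratios and list medians would change sign, its positive and negative counts would swap, and a percentile would be counted from the other end.

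Each clone was spotted 3 times, and 2253 named genes were read. The E. coli 1 h, LPS 1 h and E. coli 2 h and 4 h arrays held values for 14248, 14361 and 13914 of the 14718 spots, and the 4 h and 8 h arrays for 14130 and 13310. The median SD over the 3 spots of a clone was 0.19 on both arrays of 1 h, 0.41 on the E. coli 2 h and 4 h array, 0.60 on the 4 h array and 0.43 on the 8 h array. Before centring, the array medians were 0.07 for E. coli 1 h, 0.29 for LPS 1 h, 0.49 for E. coli 2 h and 4 h, -0.11 at 4 h and 0.12 at 8 h, and without centring each ratio and list median is higher by that amount. Ratios also depended on brightness. From the dimmest to the brightest 10% of spots, the median went from 0.90 to -0.23 on the E. coli 1 h array and from 1.22 to -0.72 on the 4 h array. Gene lists were therefore set against 10000 random lists of the same size and LPS 2 h intensity, and a list stood apart when its median lay outside the central 95% of their medians. Of 120 pairs of a list and an array, 29 stood apart, where independent random lists would give 6. Lists share members, such as CTSB and CTSS in the macrophage and lysosome lists, so this is no test of chance.

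**Figure D1:**
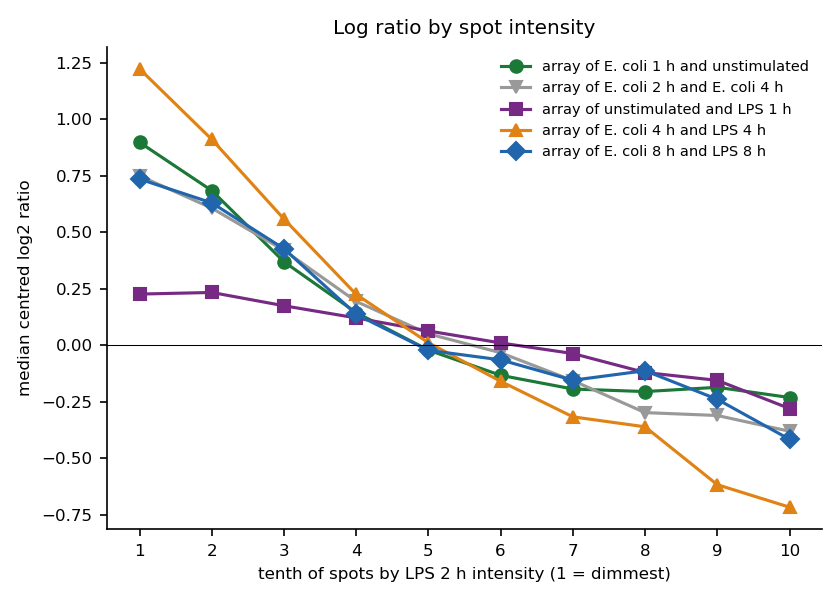
Median centred log2 ratio (vertical axis) in 10 equal classes of spots by LPS 2 h intensity (horizontal axis, 1 = dimmest), with a line for each of the 5 ratio arrays. All lines end lower than they begin, going from 1.22 to -0.72 on the 4 h array and from 0.23 to -0.28 on the LPS 1 h array.

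After 1 h of E. coli, against unstimulated cells, inflammatory cytokines and chemokines stood apart as a list. CCL20, a chemokine for CCR6-bearing lymphocytes and dendritic cells, had the largest ratio of any gene whose spots shared 1 sign, 6.0 ± 2.41 over 3 spots. IL8L1, a chicken interleukin 8 that attracts heterophils, had 3.77 ± 2.17 over 6 spots, IL1B, a proinflammatory cytokine, 3.38 ± 1.60 over 6 spots, and CCL5, a chemokine for T cells and monocytes, 3.22 ± 0.38 over 3 spots. GCLM, a subunit of the enzyme that begins glutathione synthesis, had 4.03 ± 0.19. Of 14 inflammatory cytokines and chemokines, 5 were at least 2-fold positive and 1 negative, and the list's median of 0.81 lay at percentile 99.9. The fifth positive gene was the chemokine CXCL13L2, at 2.21 ± 0.88, and the negative one IL15, a growth factor of lymphocytes, at -1.57 ± 0.32. The IL15 clone was dim (intensity percentile 2.40).

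Of 13 genes of the pathway of NF-kB, the transcription factor of inflammation, 5 were at least 2-fold positive on the E. coli 1 h array. The nuclear regulator NFKBIZ stood at 2.86 ± 0.53 and the cytoplasmic inhibitor NFKBIA at 2.18 ± 0.24. The ubiquitin ligase BIRC2 had 1.48 ± 0.33, the deubiquitinase TNFAIP3 1.22 ± 0.44 and the inhibitor NFKBIE 1.14 ± 0.25. The adaptor TRAF5 was negative at -1.09 on 1 spot of a dim clone. The list's median of 0.25 was inside the bounds at percentile 95 (0.40 and 98.2 after removal of the trend). Immediate early genes, which respond without new protein synthesis, had 4 of 13 members positive and a median of 0.37 at percentile 99.1. These were KLF2 at 1.94 ± 0.19, FOS, a subunit of the AP-1 factor, at 1.79 ± 0.11, BTG2 at 1.19 ± 1.61 and JUN, the partner of FOS, at 1.03 ± 0.80. Toll-like receptor signalling went the other way, with a median of -0.34 at percentile 0.980, although TLR15, a receptor found in birds and reptiles, had 1.69 ± 0.59. TLR1B, whose clone was dim (intensity percentile 0.36), had 1.16 ± 0.68. TLR3, a sensor of double-stranded RNA, had -2.58 ± 2.72, an SD larger than the ratio. Among 22 interferon response genes 3 were positive, IRF8 at 1.34 ± 0.31, GBP1 at 1.46 ± 0.32 and GVINP1 at 1.09 ± 0.67, and IFI27L2 was negative at -1.18 ± 0.70, with a median of -0.13 at percentile 31.6.

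Macrophage genes lay on the negative side of the E. coli 1 h array, mostly within 2-fold. Macrophage markers had a median of -0.57 at percentile 0.01 (-0.36 after removal of the trend), with the protease CTSS at -1.01 ± 0.12, the complement subunit C1QA at -0.90 ± 0.14 and LY86, a partner of a toll-like receptor homologue, at -0.86 ± 0.09, while HPGDS, a prostaglandin D synthase, had 0.88 ± 0.70. The 31 genes of lysosome and phagocytosis had a median of -0.45 at percentile 0.03 (-0.27 after removal), 1 of them past 2-fold, and PSAP, the precursor of sphingolipid activators, stood at -0.95 ± 0.14. B cell markers, a list of 5, had -0.50 at percentile 1.86, with the kinase BTK at -0.74 ± 0.10 and SH2D6 at -0.55 ± 0.16. Ribosomal proteins had -0.29 at percentile 1.97 (-0.17 after removal), with RPL7L1 at -1.52 ± 0.92 and RPS23 at 1.22 ± 1.09. Of 17 heat shock and unfolded protein genes 4 were positive, with the chaperone HSPA2 at 2.74 ± 0.37, DNAJA1 at 1.89 ± 0.63 and HSP90AB1 at 1.78 ± 0.87, and a median of 0.21 at percentile 98.2. Antigen presentation genes had -0.45 at percentile 1.18, with the activation marker CD83 at 2.00 ± 0.21 and the costimulatory receptor CD40 at -1.35 ± 1.77. Glycolysis had -0.37 at percentile 2.11, with the lactate carrier SLC16A1 at 2.07 ± 0.63 and the aldolase ALDOC at -0.84 ± 1.38. These last 3 calls ended on removal of the trend, with medians of 0.16, -0.25 and -0.24 at percentiles 94.5, 4.98 and 5.05. The 13 matrix genes, at 0.29 and percentile 92.4, then had 0.47 at percentile 98.6, with the metalloproteinases MMP27 at 2.82 on 1 spot of a dim clone and MMP9 at 1.34 ± 0.50. Oxidative and antimicrobial effectors had 5 of 28 members positive, with the nitric oxide synthase NOS2 at 1.85 ± 2.61 and the itaconate-forming enzyme ACOD1 at 1.61 ± 1.09, and a median of 0.19 inside the bounds at percentile 97.3 (0.08 after removal).

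In all, 366 of 2251 genes were past 2-fold on the E. coli 1 h array, 332 positive and 34 negative, and for 326 every spot had the same sign. After removal of the trend the split was 218 positive and 90 negative. Of the 366, 62.6% were in the dimmest 25% of genes, as were many of the largest ratios outside the lists. The positive ones included LAMP5, a lysosome-associated membrane protein, at 5.16 ± 1.52 and the sugar enzyme MPI at 3.55 ± 1.68, with RBM41, an RNA-binding protein of higher intensity, at 5.58 ± 1.36. The negative ones were led by the retinol carrier RBP4A at -3.29 ± 0.89, with the ephrin receptor EPHA4 at -2.27 ± 0.33.

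On the array of unstimulated cells and LPS 1 h, these genes had large negative ratios. CCL20 had -6.46 ± 1.64, IL8L1 -5.86 ± 1.77, IL1B -5.10 ± 1.57 and GCLM -5.78 ± 0.12, and PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, had -5.44 ± 0.97. ACOD1 stood at -4.32 ± 2.19 over 12 spots, and CH25H, which makes 25-hydroxycholesterol, at -4.17 ± 0.29. Of the 14 cytokines and chemokines 10 were at least 2-fold negative and 1, IL15 at 1.12 ± 0.30 on its dim clone, was positive. No random list reached the median of -1.61. CCL5 stood at -3.92 ± 0.08, the inflammasome product IL18 at -3.12 ± 0.30, the acute-phase inducer IL6 at -2.85 ± 0.03 and CCL4, a chemokine for monocytes, at -1.62 ± 0.16. IL13RA2, a receptor of interleukin 13, had -1.60 ± 0.26, the chemokine CCL1 -1.39 ± 0.36 and IL16 -1.07 ± 0.24.

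Of 13 NF-kB genes on the LPS 1 h array 7 were negative and none positive, and no random list reached the median of -1.38. NFKBIZ had -3.95 ± 1.15, TNFAIP3 -2.61 ± 0.48, BIRC2 -2.54 ± 0.18, TRAF5 -2.45 ± 3.49, NFKBIA -1.91 ± 0.19, CFLAR, an inhibitor of caspase 8, -1.66 ± 0.74 and NFKBIE -1.38 ± 0.66. TLR15 had -3.68 ± 0.74 and the adaptor kinase IRAK2 -1.72 ± 0.68, while TLR5, the flagellin receptor, had 1.67 ± 1.15 and the kinase MAP3K8 -1.04 ± 0.45. The median of 15 toll-like receptor genes was 0.08, at percentile 71.6 (0.0073 after removal of the trend). Among immediate early genes BTG2 had -2.05 ± 0.21, KLF2 -1.93 ± 0.61, the phosphatase DUSP1 -1.41 ± 1.23 and ATF4, a factor of the stress response, -1.37 ± 0.13, against 1.12 ± 0.15 for DUSP6. Their median of -0.45 stood at percentile 1.17, and was -0.24 at 4.96 after removal of the trend. In the interferon response list the cytokine signalling inhibitors SOCS3 and SOCS1 had -3.37 ± 1.46 and -1.92 ± 0.57, and the viral RNA sensor IFIH1 had 1.64 ± 1.08, with a median of -0.14 at percentile 6.27 (-0.04 after removal).

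Of 28 oxidative and antimicrobial effectors 8 were negative and 1 positive on the LPS 1 h array, with a median of -0.26 at percentile 2.06, which turned to 0.03 without centring. Dendritic cell markers had a median of -0.76 at percentile 0.53, from CD83 at -3.74 ± 0.18, the transcription factor ZBTB46 at -2.13 ± 0.28 and the repressor ID2 at -1.09 ± 0.12. Lysosome genes stood at 0.10 and percentile 99.9 (0.23 after removal of the trend) with none past 2-fold, led by the proton pump subunit ATP6V0E1 at 0.45 ± 0.19 and the phosphatase ACP2 at 0.43 ± 0.16. Actin and adhesion genes stood at 0.06 and percentile 99.5 (0.19 after removal), with the tetraspanin CD82 at -2.19 ± 0.32, the GTPase RHOB at 1.37 ± 0.20 and the hyaluronan receptor CD44 at -1.34 ± 0.39 over 15 spots. Macrophage markers had a median of -0.01 at percentile 86.6 (0.07 after removal), with the lipid receptor TREM2 at 1.31 ± 0.13 and CSF1R, the receptor for macrophage growth factor, at 1.17 ± 0.43. Among the glycolysis genes SLC16A1 stood at -2.34 ± 0.13 and PFKFB3 at -1.05 ± 0.12, with a median of 0.09 (0.17 after removal). Among the largest negative ratios outside the lists were those of RHBDD1, a rhomboid protease, at -5.04 ± 0.59, RSPRY1 at -4.43 ± 0.12 and RASGEF1A at -4.04 ± 0.44. The positive side was led by dim genes such as TMEM19 at 3.79 ± 4.60, with CMKLR1, the receptor for chemerin, at 2.00 ± 0.35. Past 2-fold were 251 of 2251 genes, 85 positive and 166 negative, with every spot of 1 sign for 213, and 27 of the 30 genes past 8-fold were negative. Without centring the split was 161 positive and 123 negative, and with the arrays scaled to 1 spread it was 247 and 302.

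The arrays of 1 h both held unstimulated cells, and across 2249 genes their ratios had a Pearson's r of -0.18 (95% bootstrap interval -0.25 to -0.10), or -0.34 after removal of the trend, and a Spearman's rho of -0.07. Genes are not independent replicates, and this was 1 of 10 pairs of arrays computed. CCL20, IL8L1, IL1B, GCLM and NFKBIZ were among 63 genes past 2-fold with a positive ratio on the E. coli 1 h array and a negative one on the LPS 1 h array. By the channel labels, ratios of channel 1 over channel 2 would give these signs to a gene raised by both stimuli. Opposite signs were shared by 64 genes where independent lists would give 25.5, and equal signs by 31 against 14.8. In 100 simulations with no effect, with the shared RNA in channel 2 of one array and channel 1 of the other and channel 1 as numerator, r was -0.50, 162 genes had opposite signs and 4.31 had equal signs. This r follows from giving all of the spread to RNA samples of equal deviation, so it is no measure of these data. The observed covariance was -0.12 and the simulated one -0.33. The unstimulated RNA could not be split with 1 array each, so part of the opposite signs can come from it.

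**Figure D2:**
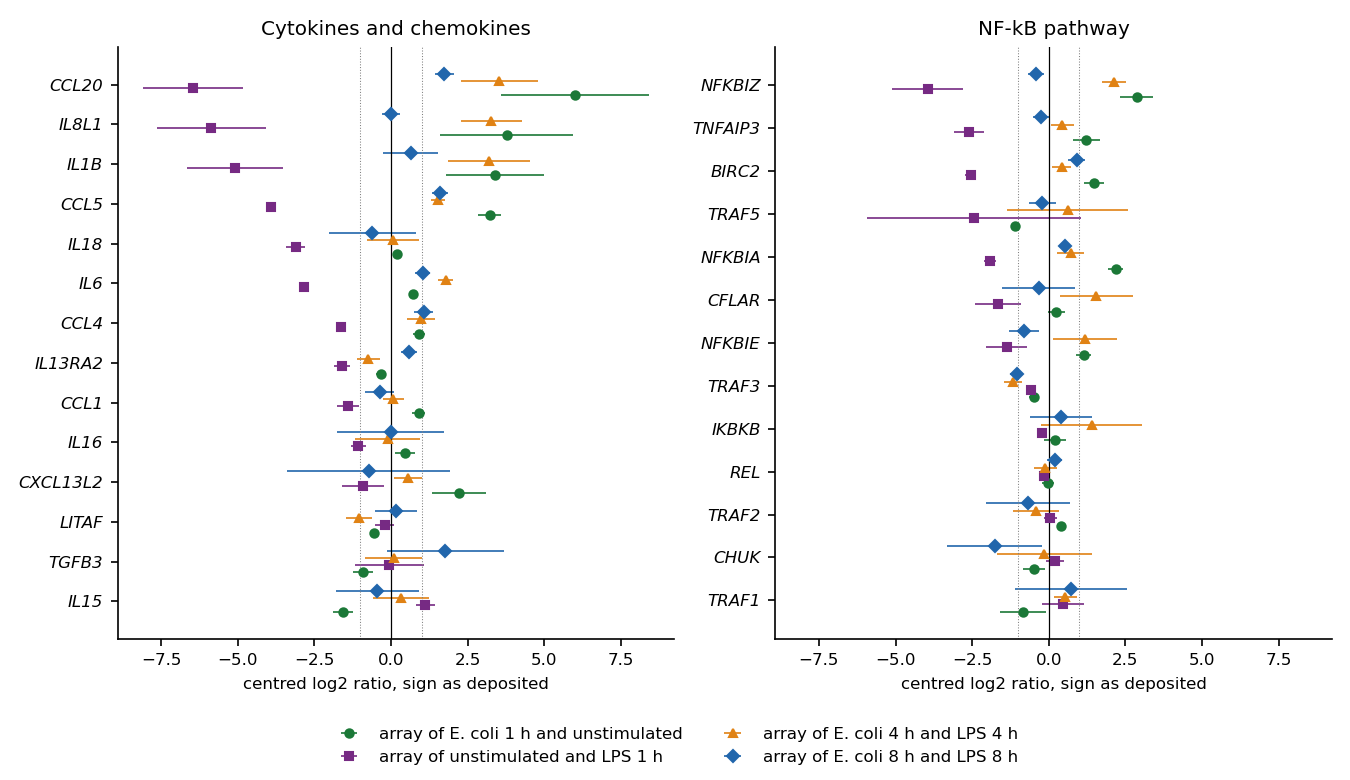
Centred log2 ratio with the sign as deposited (horizontal axis) of each gene of the cytokine list (left) and of the NF-kB list (right); points are means over spots, bars are SD over spots, and dotted lines mark 2-fold. CCL20 lies at 6.0 on the E. coli 1 h array, -6.46 on the LPS 1 h array, 3.53 at 4 h and 1.73 at 8 h.

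The array of LPS 2 h gave brightness in units the authors did not state, with a median of 0.509 over 2253 genes. Brightness also depends on the clone, so levels of different genes are given as values and not compared. SELE, the endothelial selectin that slows leukocytes on vessel walls, had 18.5 ± 1.43 and LOC395551, a chemokine of the CCL4 family, 16.2 ± 2.21. The interferon regulatory factor IRF1 had 12.4 ± 2.70, CCL20 12.2 ± 3.36, GCLM 11.4 ± 0.746 and IL1B 10.7 ± 1.46. CCL4 had 9.41 ± 0.361 and the iron store FTH1 9.35 ± 2.13. Above an intensity of 5 were 56 genes, and 12 lay below 0.

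Between E. coli 2 h and E. coli 4 h, chemokines again had some of the largest ratios, here negative. CCL4 had -2.89 ± 0.31, LOC395551 -2.41 ± 0.15, CCL5 -2.35 ± 0.22 and IL8L1 -1.80 ± 0.21, while CCL20 had -0.55 and IL1B -0.83, both within 2-fold. Of the 14 cytokines and chemokines 5 were negative and 0 positive, with TGFB3, a transforming growth factor, at -1.13 ± 0.77 and IL15 at -1.70 ± 3.28. The median of -0.66 lay at percentile 1.27, and was -0.40 at 3.90 after removal of the trend. Among NF-kB genes the kinase IKBKB had -2.29 ± 0.21, the adaptor TRAF1 -1.85 ± 1.31 and TNFAIP3 -1.40 ± 0.19, with a list median of -0.53 at percentile 4.47, which was -0.12 at 24.4 after removal of the trend and -0.03 without centring. KLF6, a zinc finger factor of early responses, had -2.17 ± 0.32 over 9 spots, KLF2 -1.41 ± 0.16 and ATF4 -1.17 ± 0.27, with a median of -0.34 at percentile 19.2 for immediate early genes, which was -0.13 after removal of the trend and 0.15 without centring.

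Macrophage markers lay on the positive side of the E. coli 2 h and 4 h array, with a median of 0.53 at percentile 99.9 (0.82 after removal of the trend). The complement subunit C1QC had 1.41 ± 1.22, the Fc receptor chain FCER1G 1.03 ± 0.37 and TREM2 0.99 ± 0.39, while the scavenger receptor MARCO had -1.01 ± 0.18. Lysosome genes had 0.06 at percentile 96.9, and 0.41 at 99.8 after removal, with ATP6V0E1 at -0.99 ± 1.37, NPC2, a cholesterol carrier, at 0.95 ± 1.30 and the protease CTSD at 0.90 ± 0.41. The interferon list had 4 positive members, GBP1 at 2.85 ± 1.83, IFIH1 at 1.49 ± 1.63, IRF8 at 1.46 ± 1.38 and PARP9 at 1.27 ± 0.15, and 2 negative ones, IRF7 at -2.24 ± 1.5 and GBP4L at -1.28 ± 0.12, with a median of 0.09 at percentile 72.1 (0.31 after removal). Toll-like receptor genes had 2 of each sign and a median of 0.06 (-0.05 after removal). MYD88, the adaptor of most toll-like receptors, had 1.30 ± 1.06, TLR2A 1.02 ± 0.39, the kinase MAPK14 -2.30 ± 0.67 and TLR1B -2.81 on 1 spot of its dim clone. In the matrix list 3 genes were negative, the gelatinase MMP9 at -1.64 ± 0.73, SERPINB2, a plasminogen activator inhibitor, at -1.33 ± 0.33 and TIMP3 at -1.30 ± 0.12, and 2 of dim clones were positive, TIMP4 at 2.96 on 1 spot and MMP1 at 1.08 ± 1.41. Their median was -0.10, and 0.0021 after removal. PCNA, the replication clamp, had 1.79 ± 0.71, the cyclin CCNB3 -1.27 ± 1.12 and CCND3 1.26 ± 0.66 in the cell cycle list, whose median of 0.61 was inside the bounds at percentile 96.8.

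Past 2-fold on the E. coli 2 h and 4 h array were 520 of 2252 genes, 333 positive and 187 negative, with every spot of 1 sign for 443. Without centring the split was 646 positive and 70 negative. The largest ratios outside the lists rested on few spots, such as PDRG1, a regulator of DNA damage responses, at 7.55 ± 6.56 over 2 spots, the translation factor EIF5B at 4.84 on 1 spot and the transcription factor TCEA1 at -3.41 ± 2.84 over 2. APCDD1, an inhibitor of Wnt signalling, had -2.64 ± 0.07 over 3 spots.

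At 4 h, with E. coli and LPS on the same array, inflammatory genes had positive ratios and macrophage genes negative ones. CCL20 had 3.53 ± 1.26, IL8L1 3.27 ± 1.00, IL1B 3.19 ± 1.34, IL6 1.78 ± 0.24 and CCL5 1.52 ± 0.24. The protease CTSS, of the macrophage and lysosome lists, had -2.35 ± 0.30. PSAP had -2.36 ± 1.01 over 12 spots and CTSD -2.13 ± 0.51, both of the lysosome list alone, whose median was inside the bounds here. Of the 14 cytokines and chemokines 5 were positive and 1, the transcription regulator LITAF at -1.05 ± 0.43, was negative, with a median of 0.44 at percentile 98.0, and at 96.6 after removal of the trend. Of the 13 NF-kB genes 4 were positive, with NFKBIZ at 2.12 ± 0.40, CFLAR, an inhibitor of caspase 8, at 1.55 ± 1.18, IKBKB at 1.40 ± 1.66 and NFKBIE at 1.17 ± 1.05, and the adaptor TRAF3 had -1.17 ± 0.30. Their median of 0.54 lay at percentile 99 (1.13 after removal). Among immediate early genes KLF2 had 1.72 ± 0.18, FOS 1.31 ± 0.25, JUN 1.10 ± 1.69, KLF10 1.05 ± 0.59 and BTG1 -1.15 ± 0.20, with a median of 0.02 at percentile 86.6, and 0.65 at 98.7 after removal of the trend. Interferon response genes had 4 positive members, SOCS3 at 2.00 ± 0.39, IFIH1 at 1.77 ± 0.81, IRF7 at 1.47 ± 1.17 and GVINP1 at 1.17 ± 0.36, and a median of -0.00 at percentile 69.7 (0.24 after removal). LBP, the plasma protein that hands LPS to its receptor, had -2.27 ± 0.42, its coreceptor LY96 -1.14 ± 0.51, and TLR15 1.31 ± 0.48. TLR3, of a dim clone (intensity percentile 3.99), had 1.16 ± 0.23 over 2 spots, which turned to -0.03 after removal of the trend.

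Of 18 macrophage markers 12 were at least 2-fold negative on the 4 h array and 1, HPGDS at 2.12 ± 1.75, was positive, with a median of -1.14 at percentile 0.03. After removal of the trend the median was -0.80 at percentile 0.01, within 2-fold, so the count of 12 belongs to ratios that keep the trend. LGMN, a lysosomal endopeptidase, had -1.99 ± 0.51 over 12 spots and the protease CTSB -1.84 ± 0.75. Lysosome genes had 13 of 31 members negative and a median of -0.57 at percentile 10.3 (-0.29 after removal of the trend), and actin genes 11 of 35 with a median of -0.59 at percentile 7.97 (-0.25 after removal). There ARPC5, a subunit of the actin-nucleating complex, had -2.76 ± 1.03, ACTR2 -1.52 ± 0.22 and ACTR3 -1.51 ± 0.41. CD74, the invariant chain of class II molecules, had -1.84 ± 0.38 and BF2, a class I molecule, -1.60 ± 0.41, with a median of -0.30 for antigen presentation (-0.04 after removal). GCLM had 2.98 ± 0.39, the peroxiredoxin PRDX1 -1.93 ± 0.52 and CYBB, the core of the phagocyte oxidase, -1.54 ± 0.63, with a median of -0.07 for effectors (0.24 after removal). In the matrix list 4 genes were positive, among them MMP27 at 3.18 ± 2.00 on a dim clone, SPP1, or osteopontin, at 1.97 ± 0.75 and MMP9 at 1.92 ± 0.49, and 2 were negative, SERPINB2 at -1.18 ± 0.76 and TIMP3 at -1.03 ± 0.27, with a median of -0.70 at percentile 6.11 (-0.31 after removal). Ribosomal proteins, with RPS25 at 2.26 ± 2.11 and RPL27 at 1.72 ± 2.95, had 0.03 at percentile 99.5 (0.34 after removal), but their median was below 0 without centring (-0.08).

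Lists named after other cells stood beside these groups on the 4 h array, and which cells expressed their members was not measured. CD3D, a chain of the T cell receptor complex, had -2.70 ± 0.75 over 2 spots of 1 clone, while the costimulatory receptor CD28 had 2.10 ± 2.49, and the T cell list had a median of 0.24 (0.46 after removal of the trend). B cell markers had -0.93 at percentile 1.5 (5.79 after removal of the trend), with the kinase SYK at -1.48 ± 1.63 and LYN at -1.06 ± 0.23. Thrombocyte markers had -1.06 at percentile 2.64 (-0.70 at 2.00 after removal), with the tubulin TUBB6 at -1.86 ± 0.59 and the GTPase RAP1B at -1.52 ± 0.47, and erythroid markers 0.88 at percentile 96.3 (99.4 after removal), with the globin HBBA at 1.79 ± 1.15 and the carbonic anhydrase CA2 at 1.35 ± 0.92. Past 2-fold were 661 of 2248 genes, 397 positive and 264 negative, with every spot of 1 sign for 542. The positive excess was not kept after removal of the trend (254 positive and 250 negative) or without the dimmest 25% of spots (230 and 257), and was smaller without centring (341 and 326). With the arrays scaled to 1 spread, 314 genes were past 2-fold, 212 positive and 102 negative, a positive share of 67.5% against 60.1% as reported. Outside the lists the largest were mostly dim, among them TRIQK at 4.67 ± 0.20 and TMOD1, a cap of actin filaments, at 4.41 ± 2.01. In the proteasome list PSMD13 had -2.67 ± 0.25, and the endocytic receptor LY75 had -2.44 ± 0.12.

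At 8 h the macrophage markers were again negative and several chemokines positive. Of 18 macrophage markers 12 were at least 2-fold negative and 0 positive, and no random list reached the median of -1.18. With the trend removed the median was -0.89 at percentile 0.02, again within 2-fold, so this count of 12 also belongs to ratios that keep the trend. CYBB had -2.26 ± 1.54, C1QC -1.97 ± 0.97, TREM2 -1.93 ± 0.86 and LY86 -1.93 ± 0.70. Lysosome genes had a median of -0.68 at percentile 0.310 (-0.38 after removal of the trend), with PSAP at -2.25 ± 0.32, CTSD at -1.73 ± 0.28 and CTSS at -1.66 ± 0.18, against 1.80 ± 0.24 for the protease CTSV. Among cytokines CCL20 had 1.73 ± 0.31, CCL5 1.59 ± 0.26, CCL4 1.06 ± 0.31, IL6 1.03 ± 0.24 and TGFB3 1.77 ± 1.90, so 5 of 14 were positive and 0 negative, with a median of 0.37 at percentile 97.8 (0.66 after removal). IL8L1 had -0.00 and IL1B 0.65, both within 2-fold.

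The 13 NF-kB genes had a median of -0.25 at percentile 39.2 on the 8 h array (-0.07 after removal of the trend), with the kinase CHUK at -1.76 ± 1.55 and TRAF3 at -1.05 ± 0.21. Toll-like receptor genes had 4 negative members and a median of -0.39 at percentile 5.58. These were TLR1B at -3.11 ± 0.19 on its dim clone, MAP3K8 at -1.61 ± 0.73, LY96 at -1.48 ± 1.20 and TLR15 at -1.12 ± 0.32. In the interferon list GVINP1, a large GTPase, had 4.12 ± 2.25, IRF8, a factor of macrophage development, 1.98 ± 0.74 and SOCS3 1.49 ± 0.14, while PARP9 had -2.95 ± 2.80 and SAMD9L -1.03 ± 1.14, with a median of 0.17. Immediate early genes had 2 members of each sign and a median of -0.17 (0.11 after removal), with DUSP6 at 1.73 ± 2.31, JUN at 1.43 ± 1.94, CEBPB, a factor of myeloid genes, at -1.17 ± 0.20 and BTG1 at -1.06 ± 0.33. Glycolysis stood apart at 0.44 and percentile 99.2, with the first enzyme HK1 at 5.94 ± 0.07 over 2 spots, PGAM1 at 1.26 ± 0.30, PFKP at 1.09 ± 0.44 and the lactate dehydrogenase LDHB at -1.04 ± 1.25. Proteasome genes had -0.51 at percentile 2.36 (4.14 after removal of the trend), with PSMD13 at -2.21 ± 2.48 and PSMB7 at -1.92 ± 1.04. Heat shock genes had -0.51 at percentile 2.55, inside the bounds (-0.33 after removal), with DNAJA1 at -1.92 ± 3.20 and HSP90B1 at -1.68 ± 0.36. Ribosomal proteins had 0.05 at percentile 96.2, and 0.27 at 98.9 after removal, with RPS16 at -1.72 ± 0.29 and RPL13 at 1.51 ± 2.38. Effectors had a median of 0.15, with PRDX1 at -1.84 ± 0.27 and FTH1 at -1.70 ± 0.24. The matrix list had 5 positive members, 1 negative one and a median of 0.13 (0.51 after removal), with MMP27 at 2.14 ± 1.67 on a dim clone, MMP9 at 2.10 ± 1.04 and SPP1 at 1.90 ± 0.25.

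CD3D, at -4.01 ± 0.76 over 3 spots, was the largest of the T cell list on the 8 h array, whose median was -0.22 (-0.08 after removal of the trend), and the coreceptor CTLA4 had 1.85 ± 0.85. S100A12, a calcium-binding protein of granulocytes, had -2.18 ± 0.11 in the heterophil list, whose median was -0.45 (-0.28 after removal). LTA4H, the enzyme that makes leukotriene B4, had -3.79 ± 0.48 over 9 spots and the endocytic adaptor SH3KBP1 -5.46 ± 0.55 over 2. The GIMAP1-GIMAP5 readthrough transcript had 10.90 ± 14.83, which 1 spot decided. Past 2-fold were 620 of 2220 genes, 333 positive and 287 negative, with every spot of 1 sign for 491. The split turned to 249 positive and 320 negative after removal of the trend, to 189 and 269 without the dimmest 25% of spots, and to 280 and 299 with the median of spots, while without centring it was 386 and 239. Of the 50 genes past 8-fold, 28 were positive and 22 negative.

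**Figure D3:**
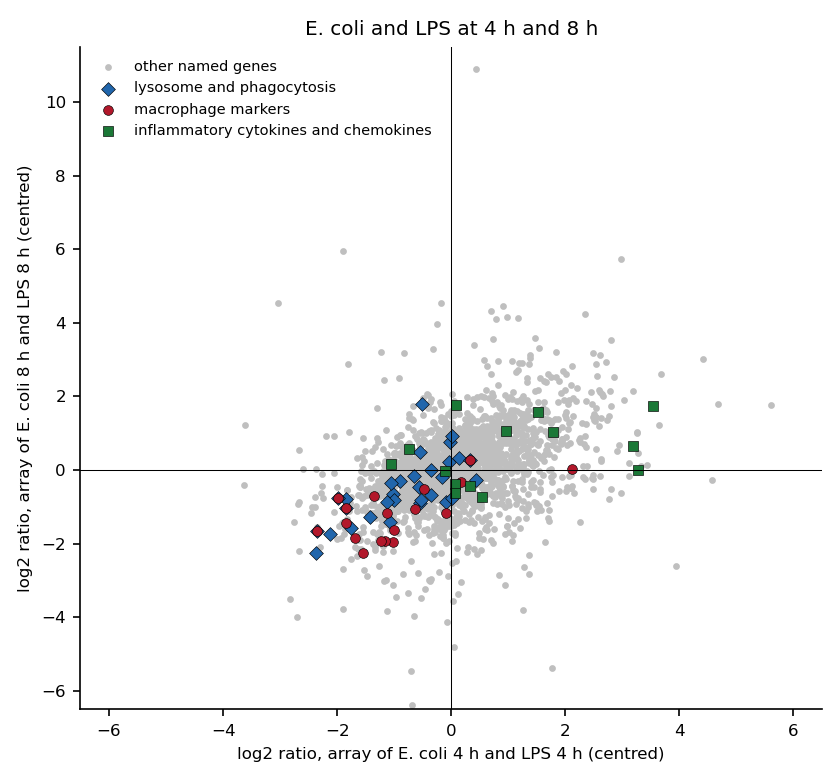
Centred log2 ratio on the 4 h array (horizontal axis) and on the 8 h array (vertical axis), 1 point per gene, with signs as deposited. Most macrophage markers lie in the lower left, with CTSS at -2.35 and -1.66, and CCL20 lies in the upper right at 3.53 and 1.73.

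Between 4 h and 8 h the ratios of E. coli and LPS had an r of 0.40 across 2216 genes (0.36 to 0.45). CTSS, PSAP, CTSD and CYBB among the negative genes and CCL20, CCL5, MMP9 and SPP1 among the positive ones were past 2-fold on both, among 262 genes with equal signs where independent lists would give 90.9. Opposite signs were held by 32 genes against 88.5. The E. coli 1 h and 4 h arrays had an r of 0.44 (0.40 to 0.48), with 183 genes of equal sign against 62.0, CCL20, IL1B, IL8L1, GCLM and NFKBIZ among them, and 20 of opposite sign against 44.5. The E. coli 2 h and 4 h array and the 4 h array both held E. coli 4 h and had an r of 0.10 (0.05 to 0.14), with -0.04 after removal of the trend. There 127 genes had equal signs against 80.3 and 71 opposite signs against 71.8. The simulation with no effect, whose r is fixed by its setting, gave an r of -0.50, 14.9 equal and 269 opposite. The observed covariance was 0.09 and the simulated one -0.48, and the shared RNA could not be split. After removal of the trend these 3 pairs, in the order given, had 167, 105 and 76 genes of equal sign against 62.0, 34.3 and 50.3. Opposite signs were then held by 30, 23 and 75 genes against 62.1, 34.1 and 50.2, so the last pair exceeded independent lists in both.

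Several lists stood apart on none of the 5 arrays before removal of the trend. Their medians ran from -0.14 to 0.17 for the interferon response, -0.23 to 0.09 for oxidative phosphorylation, -0.18 to 0.01 for cell survival and death, -0.70 to 0.29 for matrix and remodelling and 0.00 to 0.61 for the cell cycle. Among markers of other cells they ran from -0.22 to 0.24 for T cells, -0.45 to 0.41 for heterophils, -0.22 to 0.88 for erythroid cells and -1.06 to 0.04 for thrombocytes. The stromal list held 1 measured gene, the matrix protein FN1, with 0.28 ± 0.35 on the E. coli 1 h array and -1.11 ± 0.58 at 8 h. CASP1, the protease that matures IL1B and IL18, whose clone was dim (intensity percentile 1.07), had -3.61 ± 1.38 at 4 h and 1.22 ± 0.42 at 8 h. Of 1883 clones without a gene name here, 464 were past 2-fold on the E. coli 1 h array, 295 on the LPS 1 h array, 586 on the E. coli 2 h and 4 h array, 754 at 4 h and 608 at 8 h.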

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

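Of the tests in this part, those of channel order, of opposite responses and of the median and percentile after trend removal were chosen only after the result was seen, since removal of the trend was itself added after the values had been seen.

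E. coli and LPS were compared at 4 h and at 8 h, and 32 genes were past 2-fold with opposite signs at these times, which drew attention because 262 genes had equal signs. None of these differences was tested, since each time had 1 array, and they rest on both arrays having been read in the same direction. CASP1, the protease that matures IL1B, had -3.61 ± 1.38 over 2 spots at 4 h and 1.22 ± 0.42 over 3 spots at 8 h. TLR15 had 1.31 ± 0.48 over 6 spots and -1.12 ± 0.32 over 5, and CHRNB4, a subunit of a neuronal acetylcholine receptor, had 1.77 ± 0.65 and then -5.39 on 1 spot. ECT2, an exchange factor of cell division, had 3.94 on 1 spot and -2.62 ± 2.89, and SFXN1, a mitochondrial serine carrier, had 1.26 ± 0.41 and -3.80 ± 2.88. Of these 5 genes only TLR15 was bright, and CASP1, ECT2, CHRNB4 and SFXN1 lay at percentiles 1.07, 1.78, 6.52 and 15.6 of LPS 2 h intensity, with weak signal on that array.

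Opposite signs were also held by 64 genes on the E. coli 1 h and LPS 1 h arrays, a difference that was not tested, and the cytokine list had medians of 0.81 and -1.61 there. The intensity trend alone would not leave this pattern, since random lists of equal brightness had medians of -0.07 and -0.11 there with the trend kept. As the trend ran the same way on both arrays, its removal could hardly undo the opposite signs and adds little. Without it the cytokine medians were 0.99 (95% bootstrap interval -0.14 to 2.67) and -1.42 (-3.31 to -1.07). Although the first interval includes 0, these medians lay at percentiles 99.99 and 0.01 of lists of equal brightness. Whether the deposited ratio is channel 1 over channel 2 on both arrays, which would put the stimulated cells above on one and below on the other, stays open. The labels of the E. coli 1 h array are themselves in conflict, since its title names the control first while channel 1 held E. coli. Without the trend the 168 negative genes of the LPS 1 h array lay 61.5 percentile points higher in LPS 2 h intensity than the 69 positive ones (against -11.6 on the E. coli 2 h and 4 h array, or 36.9 there with the trend kept), but levels of different clones were set against each other, with no unstimulated intensity, so this decides nothing. Opposite responses to E. coli and LPS stay open, because the 11 of 14 cytokines and 9 of 13 NF-kB genes of opposite sign would be seen under either reading, and the NF-kB list, whose median on the E. coli 1 h array was at percentile 95, or 98.2 without the trend, does not settle the numerator.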

How the results depend on the processing

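Removal of the intensity trend was the alternative chosen only after the values had been seen, and its results are given last. No paired analysis was possible because each group held 1 array, so that groups shared fewer than 2 replicate numbers, and the number 1 given to each only names it. Counts of genes past 2-fold stayed within 1.5 times on all 5 arrays without centring, with the median of a gene's spots and with complete spots alone. In the order E. coli 1 h, E. coli 2 h and 4 h, LPS 1 h, 4 h and 8 h, a threshold of 1.5-fold gave 728, 1035, 501, 1157 and 1112 genes, one of 3-fold gave 171, 205, 125, 252 and 275, and counting spots singly, which multiplies the units, gave 1421, 2499, 1229, 3509 and 2653. Scaling to 1 spread gave 549 genes for LPS 1 h and 314 at 4 h, and leaving out the dimmest 25% of spots gave 188 for E. coli 1 h, with fewer genes read. Not centring adds each array's median. It moved 22 of 120 list medians beyond their 95% bootstrap intervals and turned the sign of 2 others that stood apart. On the E. coli 2 h and 4 h array the medians became -0.033 for NF-kB, 0.55 for toll-like receptors, 0.15 for immediate early genes, 0.59 for interferon, 0.17 for antigen presentation, 0.56 for lysosome, 0.21 for actin, 0.47 for ribosomal proteins, 1.10 for the cell cycle, 1.02 for macrophage and 0.29 for T cell markers. On the LPS 1 h array they became 0.37 for toll-like receptors, 0.17 for antigen presentation, 0.39 for lysosome, 0.35 for actin, 0.38 for matrix, 0.31 for heat shock, 0.38 for glycolysis, 0.30 for oxidative phosphorylation, 0.28 for ribosomal proteins, 0.32 for the proteasome and 0.33 for thrombocyte markers, and the effector list turned positive at 0.029. The ribosomal median at 4 h turned negative without centring (-0.079), with the median of spots (-0.11) and with complete spots (-0.055); the cause of the last 2 was not tested. With the median of spots HSPE1 and HK1 on the E. coli 2 h and 4 h array became 0.42 and -0.64, and RPS3 and RPL22 at 8 h -0.0029 and -0.94, while 533 of the 562 values of named genes moved by less than their SD over spots. Between the arrays of 1 h, Spearman's rho was -0.068 and r was -0.076 without the 1% of genes with the largest ratios. With the sign of 1 array turned, r was by construction 0.18 for the arrays of 1 h, -0.10 for the pair that shares E. coli 4 h, -0.40 for 4 h and 8 h, and -0.44 for E. coli 1 h and 4 h. At 1.5-fold these pairs, in this order, had 101, 341, 553 and 408 genes of equal sign and 154, 227, 117 and 74 of opposite sign. Without the trend, r for these pairs was -0.34, -0.042, 0.33 and 0.34, and the last 3 had 76, 167 and 105 genes of equal sign. List medians without the trend were -0.12 for NF-kB and 0.82 for macrophage markers on the E. coli 2 h and 4 h array, 0.23 for lysosome and 0.17 for glycolysis on the LPS 1 h array, and -0.29 for lysosome at 4 h. Actin genes had -0.058 on the E. coli 1 h array, 0.19 on the LPS 1 h array and -0.25 at 4 h, and ribosomal proteins -0.17, 0.19, 0.063, 0.34 and 0.27 on the 5 arrays in the order given. Of named genes at 4 h, TLR3, CASP9 and PSMC3IP turned to -0.030, -0.18 and -0.028, and 382 of 562 values moved by less than their SD over spots. Beyond the trend itself the cause was not tested. Of the 29 list medians that stood apart, 21 also did so without the trend, where 28 stood apart in all. What signal over background limits is set by 1 array of intensities, since the ratio arrays gave none.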

Other observations

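Of the tests in this part, those on CD3D were chosen only after the result was seen, and so were the genes named in the first paragraphs and the removal of the intensity trend, which the tests of trend and of dim spots rest on, while the test of spot position was set before.

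Among all named genes, 49 were at least 2-fold positive on the E. coli 1 h array and negative on the LPS 1 h array with every spot of 1 sign, 17 of them in the fixed lists. Of the 49, 35 had the ratio of larger size on the LPS 1 h array. Outside the lists, PLK3, a stress-activated polo-like kinase, had 2.91 ± 0.50 and -3.83 ± 0.24, and G0S2, an inhibitor of triglyceride lipase, 1.69 ± 0.43 and -3.54 ± 0.27. ACSL1, which activates long-chain fatty acids, had 1.60 ± 0.66 and -3.62 ± 0.25, and RIPK3, a kinase of necroptosis, 1.10 ± 0.16 and -2.55 ± 0.30. TNIP3, a TNFAIP3-interacting inhibitor of NF-kB, had 1.36 ± 1.38 and -3.37 ± 1.57, and INHBA, a chain of activin, 1.41 ± 0.90 and -2.17 ± 0.18.

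Comparing E. coli with LPS, 83 genes in the brighter part of the array were past 2-fold with equal signs at 4 h and 8 h, every spot of 1 sign. Of these 24 were positive and 59 negative, and 9 of the negative ones were in the macrophage or lysosome lists. This split kept the intensity trend, with medians of -0.72 and -0.42 in the brightest 10% of spots at 4 h and 8 h. Among all genes past 2-fold on both, without the rule on spots, 161 were positive and 101 negative. Among the positive ones FABP4, a fatty acid carrier, had 2.55 ± 3.38, an SD larger than the ratio, and 2.56 ± 0.85, and G0S2 had 2.66 ± 0.49 and 2.02 ± 0.21. STX11, a syntaxin of immune cell secretion, had 1.66 ± 0.28 and 1.62 ± 0.27, and ATP6V0D2, a subunit of the proton pump of osteoclasts and macrophages, 1.16 ± 0.48 and 1.61 ± 0.03. On the negative side were CHMP2B, of the endosomal sorting machinery, with -1.87 ± 0.21 and -1.74 ± 0.16, the phospholipid-binding ANXA1 with -1.55 ± 0.40 and -1.55 ± 0.57, the lysosomal membrane protein LAPTM5 with -1.76 ± 0.85 and -1.59 ± 0.78, and RNASE6, an antimicrobial ribonuclease, with -1.52 ± 0.34 and -2.72 ± 0.51. The receptor subunit CSF2RA, of the macrophage list, had -1.69 ± 0.16 and -1.86 ± 0.44.

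Ratios of the E. coli 1 h array and of the 4 h array correlated across genes, although they share no RNA sample in the labels. The intensity trend as the whole cause is argued against by an r of 0.338 after its removal (95% interval 0.283 to 0.390). Noise of dim spots is argued against by an r of 0.513 in the brighter 1127 genes (0.439 to 0.576), against -0.600 between the arrays of 1 h. For spot position, the deviations of 13721 spots from their clone means correlated at 0.0479 (0.0270 to 0.0675), above 0 and far below the 0.2 set for position as the cause, but the interval crosses the 0.05 set for excluding it, so a small part of position stays open. A response to E. coli that is stronger than that to LPS at 4 h may add to the correlation if both ratios have E. coli on the same side, and this was not tested.

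CD3D had a ratio of -2.70 ± 0.75 at 4 h and -4.01 ± 0.76 at 8 h, with an LPS 2 h intensity of 5.40, at percentile 98.0 of genes. T cells left in the cultures, for which the labels name no sort, could bring other T cell transcripts. The median of the 6 other markers was 0.80 (-0.04 to 1.81) at 4 h and -0.18 (-0.49 to 1.07) at 8 h. Each interval lay above the values of -1.35 and -2.00 that such cells were taken to need. These markers, CD28, CTLA4, GATA3, ICOS, IL2RA and TARP, had a median intensity percentile of 51.4, and 0 of them were 2-fold negative on both arrays. The ratios kept the intensity trend, and CTLA4 and ICOS were dim, at percentiles 13.5 and 23.6. As a set the markers did not follow CD3D, but dimmer markers need not follow it, so T cells are not excluded. Whether the clone reports CD3D stays open and cannot be told apart from a true ratio, since 1 clone was named CD3D.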
